A study of Mus musculus with 4 samples.

How the data were processed

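The series holds 4 single-nucleus RNA libraries of mouse heart made on the BD Rhapsody platform, in which beads in microwells tag the RNA of each nucleus with a cell label and unique molecular identifiers (UMIs). There were 2 control libraries and 2 libraries labelled Pkp2 cKO, a conditional knockout in which Pkp2 is flanked by loxP sites and removed by a tamoxifen-inducible Cre. Groups were taken from the title of each sample. The titles name the Cre line MCM in the controls too, while their genotype label reads wild type. Each library was a pool of hearts from 2 mice, per the labels' design text, and the mice were 8 weeks old with hearts collected 2 weeks after tamoxifen. A library is therefore the replicate (n = 2 per group), and the nuclei within it are not. Nuclei were released with detergent, stained with a nuclear pore antibody carrying a sample tag and sorted, per the labels' protocols, so the sort as well as the heart can set the share of each cell class. The cell type tag of the samples reads cardiomyocyte, and the same protocol describes a gate for neuronal nuclei; whether either describes the sort of these hearts is not given in the sources used here.

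The deposited values are whole-number UMI counts per gene and nucleus, in 1 matrix per library and without normalization, per the file headers and the values. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation, the handling of intronic reads and of strand, and the rule that called nuclei are not given in the sources used here. Genes were named by the symbols paired with the Ensembl identifiers in the files. Of the 44628 identifiers in the files, 27169 matched GENCODE M21 (GRCm38, the assembly that mm10 names) after version numbers were dropped, so the counting used another annotation. Coordinates are those of GENCODE M21 for genes matched by identifier. Reads of overlapping or antisense genes, and reads shared by near-identical genes, may have been counted for either gene.

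Nuclei were kept with at least 300 detected genes, at least 500 UMIs and at most 5% of UMIs from mitochondrially encoded genes, and the 0.5% of barcodes with the most UMIs in each library were removed. The mitochondrial limit removed the most: 49.6% of barcodes in control 1, 53.8% in cKO 1, 50.9% in control 2 and 48.8% in cKO 2 were above it. Doublets were scored with Scrublet (scanpy 1.11.5, expected share 6%) in each library. The automatic threshold marked 0.101%, 0.207% and 0.109% of the nuclei of control 1, cKO 1 and control 2, under the minimum of 0.5% for a working threshold, so the 6% highest scores were removed there. In cKO 2 the automatic threshold held and removed 14.4%. This left 2805, 3642, 6024 and 6201 nuclei in control 1, cKO 1, control 2 and cKO 2.

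Counts were scaled per nucleus and log-transformed, 2000 variable genes were chosen within libraries, and nuclei of all libraries were clustered together from 30 principal components and 15 neighbours with the Leiden method at resolution 1 (leidenalg 0.10.2, seed 1), without batch integration. This gave 30 clusters. A cluster took a class name from fixed marker lists where at least 3 markers were detected in at least 10% of its nuclei at over 2 times the level in the other nuclei. It stayed unnamed where an unrelated class had at least 3 markers and over 50% as many as the best, where its 10 leading genes held more markers of another class, or where it was shallow with no own marker among them. The details of this naming rule were written after the data were seen; the marker lists were not. The names cardiomyocyte, fibroblast, endothelial, mural and macrophage mean nuclei that are like those types by these markers. Endothelial nuclei include endocardial but not lymphatic nuclei, and mural nuclei join pericytes and smooth muscle.

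Counts were summed per library and class, because nuclei are not replicates. The sums were tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood test after TMM normalization and edgeR's expression filter, with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. CPM values of single genes in a class are scaled with TMM factors. Summed CPM of markers, CPM of nuclei with and without Esr1 UMIs and ratios of pooled counts use raw totals without that scaling. Errors are SD over 2 libraries for CPM and shares and SE for log2 fold changes. The SE was derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F. Numbers of nuclei per class were tested with the same model on library totals, and a two-sided exact permutation test of the log shares was run beside it; with 2 against 2 libraries its smallest p is 0.333, so it cannot pass 0.05. Gene lists, 24 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 in each class with at least 5 tested members, 119 tests in all, adjusted together. Of these 40 passed, 31 of them upward. The tests were repeated with an estimated correlation, under which 0 of the 119 had an adjusted p under 0.05 and 10 an unadjusted p under 0.05. The planned test fry of limma was run beside camera, without adjustment. For lists that passed camera its p lay on both sides of 0.05. Fry gave 0.0120 for the fetal and stress programme and 0.140 for glycolysis in cardiomyocytes. It gave 0.0164 for fibroblast activation in fibroblasts and 0.376 for collagens and matrix in endothelial nuclei. Whether an effect differed between cardiomyocytes and another class was tested by an interaction term in a model of both classes with the library as a block.

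The rule for named genes took genes past the threshold whose cKO libraries both lay above, or both below, both control libraries, with a mean of at least 10 CPM and an established symbol. From these it took the 12 largest rises and 12 largest falls in cardiomyocytes and up to 6 of each in the other classes, with Pkp2 in every class and, of each list described, 2 to 4 of the members with the smallest p. The marker lists, gene lists, filters, tests and this rule were fixed before the data were examined.

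The tests were checked on simulated counts drawn from the means, fitted dispersions and library sizes of each class. Genes were drawn independently, so effects shared by genes of a library were not simulated. Changes in the class tests were planted outside the genes of lowest expression. Of genes changed 4-fold, 92% were called in cardiomyocytes (15248 genes), 88% in fibroblasts (11855), 92% in endothelial nuclei (11249), 85% in mural nuclei (8530) and 88% in macrophages (8389). Of genes changed 2-fold, 51%, 38%, 37%, 20% and 16% were called in the same order, so changes of that size were often missed. Of the unchanged genes 6, 4, 5, 8 and 1 were called in the same order. The interaction test of cardiomyocytes against fibroblasts was simulated with the dispersions of cardiomyocytes in both classes. On 14847 genes it called 59.2% of those changed 4-fold and 14 unchanged genes.

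Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, the replicate number as a block, stricter nucleus filters (1000 UMIs and 500 genes, or at most 1% mitochondrial UMIs), no doublet removal, clustering of each library alone, leaving out genes whose mean CPM in a class was under 0.2 of that in cardiomyocytes, shares among nuclei other than cardiomyocytes, and leaving out each library in turn. Added after the data were seen were a mitochondrial limit of 20%, an equal doublet share of 6% in every library, leaving out clusters with over 80% of their nuclei from 1 library, and joining the unnamed clusters that best matched the macrophage list to the macrophages. Doublets were scored anew under each nucleus filter. At the 20% limit the automatic threshold held in control 2, where it removed 10.9%, and not in cKO 2, where 6.0% was removed. With at least 1000 UMIs and 500 genes it removed 8.83% in control 2 and 13.9% in cKO 2, and at the 1% limit 5.42% in control 1, 1.27% in cKO 1 and 0.538% in cKO 2. These alternatives therefore change 2 choices. Groups of 2 libraries were too small for a check of outliers and for counting other splits of the samples. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.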

Results

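Nuclei of whole mouse hearts were profiled to compare hearts in which Pkp2 had been targeted for deletion with control hearts. The groups may differ in expression of a Cre transgene too, as given with Esr1 and Gh below. The design cannot tell effects of such a difference from those of Pkp2. Pkp2 encodes plakophilin 2, a protein of the desmosome, which couples heart muscle cells to each other. Loss of function in PKP2 is a known cause of arrhythmogenic cardiomyopathy. The control libraries held 5947 and 13097 barcodes with 13491201 and 35204091 UMIs. The libraries labelled Pkp2 cKO held 8424 and 14238 barcodes with 20992683 and 40536562 UMIs. After filtering, 2805 and 6024 control nuclei and 3642 and 6201 cKO nuclei remained. The design text names 1 male and 1 female mouse per pool. Xist, which is transcribed from the inactive X chromosome of female cells, gave 5 and 9 UMIs in the control and 5 and 12 in the cKO libraries. Y-linked genes together gave 3299 and 7905 UMIs in the control and 4868 and 8840 in the cKO libraries.

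Pkp2 transcript did not differ detectably between the groups in cardiomyocytes. Pkp2 (ENSMUSG00000041957, GRCm38 chromosome 16, 16213318 to 16272712) measured 570 and 557 CPM in the control and 619 and 596 CPM in the cKO libraries. Its log2 fold change was 0.11 (SE 0.14, adjusted p = 0.815). In the other classes its log2 fold change was -0.29 in fibroblasts, -0.29 in endothelial nuclei, 0.21 in mural nuclei and -0.95 in macrophages, with adjusted p of 0.734, 0.817, 0.999 and 0.476. The labels do not say which part of the gene is flanked by loxP sites or which part of the transcript was counted. These counts therefore do not check the deletion, and the cKO libraries are named by their label throughout.

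The cell classes differed in their shares between the groups, with fewer cardiomyocytes and more endothelial nuclei in the cKO libraries. Cardiomyocytes made up 46.3% ± 6.61 (SD, n = 2) of control nuclei and 28.0% ± 5.38 of cKO nuclei, a log2 ratio of -0.72 (edgeR adjusted p = 0.00918). Endothelial nuclei, which line the blood vessels and heart chambers, made up 12.9% ± 2.36 of control and 27.6% ± 4.6 of cKO nuclei, a log2 ratio of 1.1 (adjusted p = 0.000695). Lymphatic endothelial nuclei made up 1.05% ± 0.275 and 2.05% ± 0.00796 (log2 ratio 0.97, adjusted p = 0.00918). Mural nuclei, the pericytes and smooth muscle of vessel walls, made up 8.74% ± 1.63 of control and 6.05% ± 0.204 of cKO nuclei (log2 ratio -0.53, adjusted p = 0.0397). Fibroblasts (17.5% ± 2.47 and 19.6% ± 3.39, adjusted p = 0.517) and macrophages (6.71% ± 0.367 and 6.71% ± 1.34, adjusted p = 0.986) did not pass the test. Lymphocytes, at 0.555% and 0.481%, did not pass it either (adjusted p = 0.517). Epicardial nuclei rose from 0.128% to 0.333% (adjusted p = 0.0251), on 3 and 9 control and 9 and 26 cKO nuclei. The exact permutation test gave its smallest possible p, 0.333, for the 5 shares that passed. Shares sum to the whole library, so they do not move independently, and they follow the sort and the filters as well as the tissue. The cell type tag of all samples reads cardiomyocyte, although every library held the classes above, so which nuclei the sort kept is not clear.

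**Figure D1:**
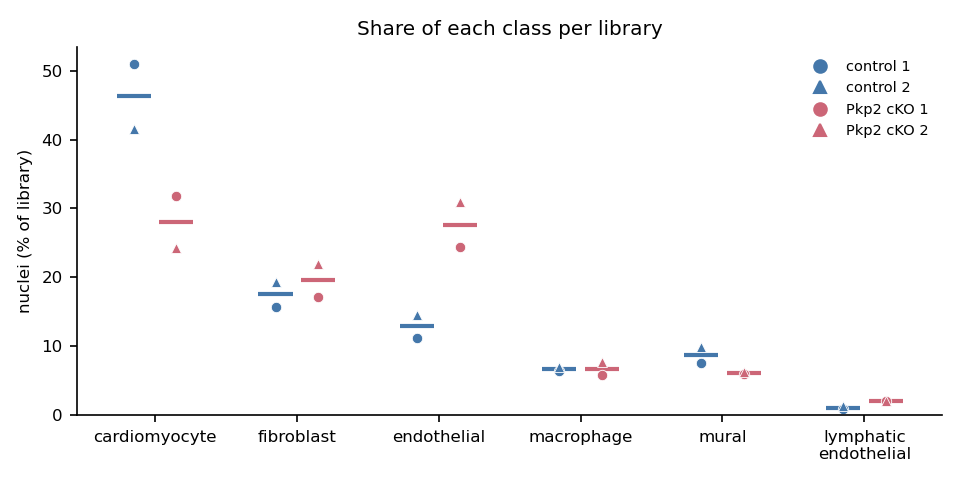
Share of nuclei in 6 classes (y axis, percent of the nuclei of a library; x axis, class). Points are libraries (blue control, red Pkp2 cKO; circles library 1, triangles library 2) and lines are group means, with cardiomyocytes at 46.3% in control and 28.0% in cKO libraries and endothelial nuclei at 12.9% and 27.6%.

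The call on the cardiomyocyte share was lost without control 1 (log2 ratio -0.57), control 2 (-0.86) or cKO 2 (-0.54). It was also lost with at least 1000 UMIs per nucleus (-0.85) and with each library clustered alone (-0.50). The endothelial call was lost without control 1 (0.93) or control 2 (1.30) and with at most 1% mitochondrial UMIs (1.72), and its log2 ratio was 0.45 at the 20% mitochondrial limit, where doublet removal also differed, at 10.9% in control 2 and 6.0% in cKO 2. The mural call was lost without control 1 (-0.71), cKO 1 (-0.50), control 2 (-0.33) or cKO 2 (-0.57). It was also lost with at least 1000 UMIs (-0.26), without doublet removal (-0.46) and with an equal doublet share in every library (-0.39). The share of mural nuclei turned higher in the cKO libraries with at most 1% mitochondrial UMIs (0.35). Among nuclei other than cardiomyocytes, fibroblasts were lower in the cKO libraries, with a log2 ratio of -0.26, and macrophages with -0.43. With the unnamed clusters that best matched the macrophage list joined to them, macrophages were higher, at 8.73% and 9.51% of all control nuclei and 14.9% and 12.2% of all cKO nuclei, and passed (log2 ratio 0.57). Unnamed clusters held 6.04% ± 0.681 of control and 9.12% ± 4.27 of cKO nuclei.

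In cardiomyocytes, 203 genes rose and 239 fell in the cKO libraries among 15248 tested, and the natriuretic peptides and the slow myosin were among the largest rises. Nppa, the atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), rose from 12.4 ± 3.75 CPM (SD, n = 2) to 97.9 ± 8.66 CPM, a log2 fold change of 2.93 (SE 0.22, adjusted p = 0.000884). Nppb, the brain natriuretic peptide, rose from 105 ± 43.4 to 670 ± 238 CPM (log2 fold change 2.69, SE 0.32, adjusted p = 0.00368). Myh7, the beta myosin heavy chain (chromosome 14, 54970684 to 54994626), rose from 287 ± 66.3 to 1362 ± 210 CPM (log2 fold change 2.25, SE 0.20, adjusted p = 0.00145). Whether reads of a transgene add to the Myh7 counts stays open, as given with Esr1 below. The stress-induced cytokine Gdf15 (log2 fold change 3.91), the nicotinamide riboside kinase Nmrk2 (3.29) and the skeletal alpha-actin Acta1 (1.99) rose as well. So did the kinase Pak3 (2.31), Gask1b (2.29), Ccdc68 (2.15) and the prothrombinase Fgl2 (2.07).

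Acsm5, a mitochondrial medium-chain acyl-CoA synthetase, fell in cardiomyocytes from 25.1 ± 4.28 to 3.2 ± 0.218 CPM (log2 fold change -2.94, SE 0.26, adjusted p = 0.00134). Mylk4, of the myosin light chain kinase family, fell from 281 ± 23.2 to 62.5 ± 9.10 CPM (log2 fold change -2.17). Pfkfb1, which sets the level of a glycolysis activator, fell from 155 ± 2.22 to 34.9 ± 1.65 CPM (log2 fold change -2.15). The chloride channel Clcn1 (-2.37), the potassium channel subunit Kcnv2 (-1.88) and Strit1 (-2.04), a micropeptide that activates the calcium pump of the sarcoplasmic reticulum, fell too. Further log2 fold changes were -2.15 for Arrdc2, -1.87 for Lgi1, -1.79 for the lipoxygenase Alox5, -1.76 for Cntn5, -1.76 for Ano5 and -1.63 for Rp1. All 24 genes named by the rule in this class stayed past the threshold in the same direction under every alternative that gave a value.

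The highest rises of all named in cardiomyocytes were those of Gh, the growth hormone gene (chromosome 11, 106300271 to 106301865), and Esr1, the estrogen receptor alpha gene (chromosome 10, 4611593 to 5005614). Esr1 rose from 69.8 ± 8.25 to 3468 ± 208 CPM (log2 fold change 5.64, SE 0.20, adjusted p = 6.88e-06). Gh rose from 2.09 ± 1.36 to 109 ± 29.8 CPM (log2 fold change 5.89, SE 0.37, adjusted p = 0.000574). Both effects were larger than in fibroblasts, by 5.43 on the log2 scale for Esr1 and 4.79 for Gh (interaction adjusted p = 6.80e-45 and 0.000415). In cardiomyocyte nuclei with at least 3000 UMIs, the mean was 0.314 and 0.302 Esr1 UMIs in the control and 19.7 and 20.9 in the cKO libraries. The log2 fold change of Gh in cardiomyocyte nuclei was 6.57 without control 1 and 5.14 without control 2. Counts do not tell transcripts of an endogenous gene from those of a transgene that carries part of it. Myh7 was also higher in the cKO nuclei with Esr1 UMIs than in those without, at 1899 against 650 CPM in cKO 1 and 1440 against 552 CPM in cKO 2. All such control nuclei gave 336 and 230 CPM of Myh7. Nppb was lower in the cKO nuclei with Esr1 UMIs, at 798 against 993 and 446 against 664 CPM, as was Ankrd1, at 1770 against 2245 and 1455 against 2094 CPM. Nppa was nearly equal in cKO 1, at 95.6 against 100.5 CPM, and lower in cKO 2, at 89.5 against 153 CPM. These differences in CPM between nuclei were not tested. Presence in the same cKO nuclei was compared at matched depth, after the gene results were seen. The odds ratio of Esr1 with Myh7 was 4.18 in cKO 1 and 4.36 in cKO 2. That of Esr1 with Nppb was 0.736 and 0.504.

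The nuclei of cardiomyocytes fell into partly different clusters in the 2 groups. A cluster with Pfkfb1, Mylk4 and Cntn5 among its leading genes held 61.4% and 71.0% of control cardiomyocytes and 4.40% and 6.45% of those in the cKO libraries. A cluster with Nppb, Nppa and Ankrd1 among its leading genes held 2.94% and 1.64% in the control and 30.3% and 36.5% in the cKO libraries. Leading genes were taken over all nuclei of a cluster. Of control cardiomyocyte nuclei with at least 3000 UMIs, 86.7% and 84.3% held no Esr1 UMI. The clusters led by Esr1 held nuclei of both groups. That with Gh and Myh7 next held 12.5% and 15.2% in the control and 28.2% and 35.0% in the cKO libraries. That with Myh7 and Synpo2l next held 19.9% and 9.38% in the control and 33.5% and 19.0% in the cKO libraries, and that with Abra next 2.59% and 2.39%, and 3.53% and 2.99%. Between 4985310 and 10911418 counts were summed per library. DESeq2 called 502 genes, and 2181 genes had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap in any of the 442 changed genes, and among all genes tested they did not overlap in 43.4%, against 33.3% by chance. The share among all genes was 42.7% in fibroblasts, 38.5% in endothelial nuclei, 32.8% in mural nuclei and 38.3% in macrophages.

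**Figure D2:**
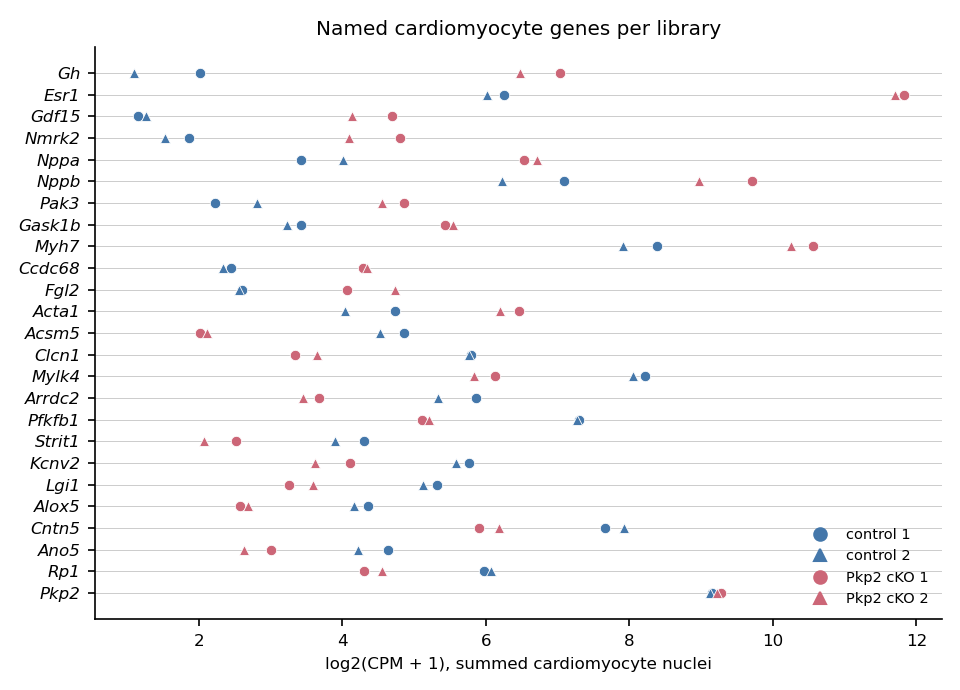
Expression of the named cardiomyocyte genes and Pkp2 in each library (x axis, log2 of CPM plus 1 in summed cardiomyocyte nuclei; y axis, gene). Points are libraries (blue control, red Pkp2 cKO; circles library 1, triangles library 2); the groups are separate for each gene named by the rule, such as Nppa with means of 12.4 and 97.9 CPM.

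Among the gene lists in cardiomyocytes, the fetal and stress programme had the smallest p. Of its 18 tested members 7 rose and 11 did not pass, while 11 rose when adjusted over the list alone. Those past the threshold included Nppa, Nppb, Myh7 and Ankrd1 (log2 fold change 1.55), DESeq2 called 9, and the median was 0.77 (camera adjusted p = 5.46e-25, and adjusted p = 0.584 with an estimated correlation). Immediate early genes, induced within minutes of a stimulus, had 4 of 12 members up, or 9 adjusted over the list alone and 6 by DESeq2. Fos (2.99), Nr4a1 (1.71), Btg2 (1.52) and Junb (1.49) passed (camera adjusted p = 9.03e-11, and adjusted p = 0.584 with an estimated correlation). Of 19 targets of the Hippo-YAP pathway and of mechanical load, 4 rose: Ankrd1, Tgfb2 (1.64), Ccn2 (1.69) and Ccn1 (1.22). Adjusted over the list alone, 5 rose and 1 fell, and the median was 0.05 (camera adjusted p = 0.00693, and adjusted p = 0.707 with an estimated correlation). Of 13 genes of the integrated stress response, Gdf15 was the 1 that rose, also adjusted over the list alone (camera adjusted p = 0.0221, and adjusted p = 0.707 with an estimated correlation).

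Of the lists of fuel use in cardiomyocytes, glycolysis and fatty acid oxidation passed camera in opposite directions, with few members past the threshold, and the difference between the lists was not tested. Of 20 glycolysis genes, 3 rose, or 7 adjusted over the list alone, and 4 changed by DESeq2. They were the phosphofructokinase Pfkp (1.52), the hexokinase Hk1 (1.01) and the glucose transporter Slc2a1 (1.26), and the median was 0.43 (camera adjusted p = 1.81e-06, and adjusted p = 0.707 with an estimated correlation). Of 29 genes of fatty acid oxidation, 3 fell, while adjusted over the list alone 6 fell and 1 rose, and 6 changed by DESeq2. They were the uncoupling protein Ucp3 (-0.73), the carnitine carrier Slc25a20 (-0.69) and the thiolase Acaa2 (-0.66), and the median was -0.26 (camera adjusted p = 0.000436, and adjusted p = 0.584 with an estimated correlation). Of 24 nuclear genes of oxidative phosphorylation, 0 changed by edgeR, 0 by DESeq2 and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Their median was -0.03 (camera adjusted p = 0.615, and adjusted p = 0.875 with an estimated correlation).

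Genes of the intercalated disc, where Pkp2 acts, did not pass as a list in cardiomyocytes. Of 20 tested, Xirp1 (0.92) and the beta-catenin gene Ctnnb1 (1.06) rose, 4 rose when adjusted over the list alone, DESeq2 called 4, and the connexin Gja1 stood at 0.63 with an adjusted p of 0.0547. The list had a camera adjusted p of 0.110, and adjusted p = 0.707 with an estimated correlation. It passed without cKO 1 (0.0383), and the adjusted p was 0.0383 to 0.321 over the left-out libraries. Of 25 ion channel and calcium handling genes, the potassium channel Kcnj3 fell (-0.88), or 2 genes adjusted over the list alone, and 2 changed by DESeq2 (median -0.11, camera adjusted p = 0.243, and adjusted p = 0.736 with an estimated correlation). Of 24 sarcomere genes 0 changed by edgeR and 2 by DESeq2, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 2 of them rose and 1 fell (camera adjusted p = 0.542, and adjusted p = 0.790 with an estimated correlation). Of 16 cell death genes 0 changed by edgeR, by DESeq2 or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.593, and adjusted p = 0.790 with an estimated correlation).

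Fibroblasts showed a rise of matrix and activation genes, with 288 genes up and 175 down among 11855 tested. Postn, which encodes periostin, a matrix protein of activated fibroblasts (chromosome 3, 54361109 to 54391037), rose from 50.6 ± 14.0 to 1049 ± 355 CPM (log2 fold change 4.45, SE 0.33, adjusted p = 3.49e-05). The activation marker Cthrc1 gave 3 counts over the control libraries and was 30.8 times as high in the cKO libraries (95% counting interval 10.3 to 151). The cytokine Il6 also gave 3 control counts and was 45.3 times as high (15.3 to 221). The collagen prolyl hydroxylase P4ha3 gave 2 control counts and was 24.1 times as high (6.46 to 202), and the adenylate kinase Ak5 gave 1 and was 63.0 times as high (11.1 to 2512). The cholesterol hydroxylase Ch25h gave 0 control counts and was at least 19.5-fold higher, with 3 counts over the control group as the floor. These ratios pool the counts of a group, and intervals and floors cover counting error only. The mean CPM over libraries was 0.803 and 46.1 for Cthrc1, 2.22 and 40.6 for Il6, 1.95 and 23.1 for P4ha3 and 0.98 and 27.8 for Ak5 in control and cKO fibroblasts. For Il6 the SD over the cKO libraries was 44.9 CPM, above its mean. Its pooled ratio therefore does not describe both cKO libraries alike. Hsd11b1, which regenerates active glucocorticoid, fell from 378 ± 5.53 to 38.9 ± 21.1 CPM (log2 fold change -3.19, SE 0.30, adjusted p = 7.34e-05). The other named falls were Tll2 (-3.79), the glutamate receptor Grm8 (-3.47), the aldehyde oxidase Aox3 (-3.45), Blnk (-3.30) and the enkephalin precursor Penk (-3.15).

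Most members of the fibroblast activation list rose in fibroblasts, 21 of the 27 tested, while adjusted over the list alone 22 rose and 1 fell, and 21 changed by DESeq2. Comp (3.41), Ddah1 (3.66) and the mechanosensitive channel Piezo2 (3.18) stood beside Postn, and the median was 2.07 (camera adjusted p = 2.65e-69, and adjusted p = 0.584 with an estimated correlation). Of 31 collagens and matrix genes 21 rose, or 24 adjusted over the list alone, and 19 changed by DESeq2. Among them were Col14a1 (2.70), Thbs1 (2.82), the crosslinking enzyme Lox (3.25) and Col12a1 (3.2), and the median was 1.40 (camera adjusted p = 7.46e-42, and adjusted p = 0.584 with an estimated correlation). Of 13 immediate early genes 8 rose, or 10 adjusted over the list alone and 3 by DESeq2, among them Egr2 (3.29), Junb (1.68) and Egr1 (2.05) (camera adjusted p = 5.64e-10, and adjusted p = 0.707 with an estimated correlation). Of 19 inflammatory genes Ptgs2 (3.58), Il6 and Cxcl1 (2.72) rose, or 4 adjusted over the list alone and 1 by DESeq2 (camera adjusted p = 0.000252, and adjusted p = 0.707 with an estimated correlation). That call was lost without cKO 2 (0.113), and the adjusted p was 4.39e-12 to 0.113 over the left-out libraries. The fetal and stress list had 4 of 16 members up, or 5 adjusted over the list alone, and 3 changed by DESeq2. Of these Ccn2 (2.99), Timp1 (3.75) and Tnc (2.85) are also known in matrix remodelling (camera adjusted p = 3.49e-07, and adjusted p = 0.707 with an estimated correlation).

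Fibroblasts also fell into different clusters in the 2 groups. A cluster with Cilp, Postn and Comp among its leading genes held 14.0% and 8.97% of control fibroblasts and 91.5% and 80.5% of those in the cKO libraries. A cluster with Scara5 and Hsd11b1 among its leading genes held 85.5% and 91.0% of control and 7.35% and 10.7% of cKO fibroblasts. A smaller cluster led by Cxcl1 and Il6 took 93.0% of its 129 nuclei from cKO 2. Heart muscle markers summed to 8248 and 7464 CPM in control and 7734 and 6115 CPM in cKO fibroblasts. Between 516726 and 3239977 counts were summed per library. DESeq2 called 324 genes, without Il6, P4ha3 and Tll2. The number of fibroblast genes changed was 304 without control 2, where P4ha3 and Tll2 lost their call. Without cKO 2 the log2 fold change was -3.98 for Hsd11b1 in fibroblast nuclei, -5.26 for Grm8 in fibroblast nuclei and -4.57 for Aox3 in fibroblast nuclei, and Il6, which measured 40.6 ± 44.9 CPM in the cKO libraries, gave no value.

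In endothelial nuclei 12 genes rose and 13 fell among 11249 tested. Selp, which encodes P-selectin, an adhesion molecule for white blood cells, rose from 7.53 ± 6.94 to 95.7 ± 75.7 CPM (log2 fold change 3.33, SE 0.58, adjusted p = 0.0200). Lrg1, a secreted glycoprotein that promotes vessel growth, rose from 11.9 ± 1.92 to 66.9 ± 13.9 CPM (log2 fold change 2.39, SE 0.35, adjusted p = 0.0155). Cmah (1.68), Fam110d (1.47), the phospholipid flippase Atp8b1 (1.46) and the basement membrane collagen Col15a1 (1.38) also rose. The metalloproteinase inhibitor Timp4 fell from 212 ± 16.0 to 56.4 ± 2.25 CPM (log2 fold change -1.90, SE 0.23, adjusted p = 0.00281). The other named falls were Dixdc1 (-2.21), Lsamp (-1.73), the potassium channel Kcnd3 (-1.65), Ralgps2 (-1.57) and Plac9 (-1.55).

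Of 20 endothelial activation genes Selp alone passed in endothelial nuclei, 6 rose when adjusted over the list alone, and DESeq2 called 1, which was not Selp. Col4a1 stood at 0.95, Edn1 at 1.34 and Icam1 at 0.93 (camera adjusted p = 1.03e-06, and adjusted p = 0.584 with an estimated correlation). The 24 interferon response genes all had positive log2 fold changes, with a median of 0.42. Of these 0 passed by edgeR and 0 by DESeq2, 4 had an unadjusted p under 0.05 and Ifi44 (1.33) passed adjusted over the list alone (camera adjusted p = 1.56e-05, and adjusted p = 0.584 with an estimated correlation). Lists of heart muscle genes passed camera downward in endothelial nuclei. Of 24 sarcomere genes 0 changed by edgeR, with a median of -0.30 (camera adjusted p = 9.87e-05, and adjusted p = 0.707 with an estimated correlation). Of 22 ion channel and calcium handling genes 1 fell, with a median of -0.31 (camera adjusted p = 0.00024, and adjusted p = 0.619 with an estimated correlation). The cause of these falls was not tested. Of 27 collagen and matrix genes, Col15a1 and Sparc (1.13) rose, or 4 adjusted over the list alone and 4 by DESeq2 (camera adjusted p = 0.000492, and adjusted p = 0.736 with an estimated correlation). That call was lost without cKO 1 (0.351) or control 2 (0.401), and the adjusted p was 1.61e-08 to 0.401 over the left-out libraries.

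The endothelial class also shifted between clusters. A cluster with Kirrel3, Col13a1 and Slco2a1 among its leading genes held 5.10% and 9.37% of control and 19.1% and 23.6% of cKO endothelial nuclei. When cKO 1 was clustered alone, a cluster led by Kirrel3 had Selp and Cmah among its leading genes. A cluster led by Nrg1 and Npr3, genes of the endocardium, held 16.2% and 17.8% of control and 8.68% and 8.62% of cKO endothelial nuclei. A cluster led by Selp took 98.0% of its 200 nuclei from cKO 2. The named genes were not tested within clusters. Heart muscle markers summed to 11401 and 8777 CPM in control and 7911 and 6692 CPM in cKO endothelial nuclei. Between 385416 and 3634012 counts were summed per library. The number of endothelial genes changed was 0 by edgeR with each library clustered alone, beside 971 genes with an unadjusted p under 0.05 and 43 called by DESeq2 in the joint clustering. The number was 83 without control 1, 58 without cKO 1, 51 without control 2 and 44 without cKO 2. Without control 2 the calls on Cmah, Fam110d, Col15a1, Dixdc1 and Ralgps2 were lost, and DESeq2 did not call Selp. The log2 fold change of Selp in endothelial nuclei was 2.10 without cKO 2, 3.92 without cKO 1 and 5.24 without control 2.

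In mural nuclei 2 of 8530 genes rose, and 410 had an unadjusted p under 0.05. Acta2, the smooth muscle actin, rose from 64.2 ± 7.45 to 240 ± 31.4 CPM (log2 fold change 1.93, SE 0.31, adjusted p = 0.0275). The orphan receptor Gpr176 rose from 16.7 ± 11 to 92.5 ± 21.5 CPM (log2 fold change 2.79, SE 0.48, adjusted p = 0.0434). A smooth muscle cluster with Myh11 and Acta2 among its leading genes held 3.29% and 4.19% of control and 8.84% and 11.5% of cKO mural nuclei. A larger cluster with Il34, Vtn and Colec11 among its leading genes held 14.6% and 24.5% of control and 21.9% and 2.34% of cKO mural nuclei, so cKO 2 stood apart from the other 3 libraries there. Between 256539 and 1077167 counts were summed per library. The number of mural genes changed was 0 without control 1 or control 2 by edgeR, 68 without cKO 1 and 26 without cKO 2, and 0 by DESeq2 with all libraries. The calls on Acta2 and Gpr176 were lost without control 1 or control 2, and that on Acta2 also at the 20% mitochondrial limit and its other doublet shares, with a log2 fold change of 0.36. In simulated mural counts 8 unchanged genes were called. There 100 genes changed 2-fold and 100 changed 4-fold were planted, so that number does not carry over to the 2 calls here.

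In macrophages 14 genes rose and 9 fell among 8389 tested, with rises in genes of lipid-laden macrophages. Gpnmb, a glycoprotein of such cells, rose from 4.90 ± 6.93 to 184 ± 1.70 CPM (log2 fold change 4.63, SE 0.51, adjusted p = 0.000436). Spp1, which encodes osteopontin, gave 1 control count and was 33.6 times as high in the cKO libraries (95% counting interval 5.75 to 1355), from pooled counts, with a mean over libraries of 2.42 and 46.5 CPM. Cd300lf (3.59), Nxpe5 (2.96), St18 (2.79) and the lysosomal protease Ctsd (2.72) rose too. Timd4, a marker of long-lived resident macrophages, fell from 135 to 33.3 CPM (log2 fold change -1.89, SE 0.36, adjusted p = 0.0339). The other named falls were Retnla (-3.18) and Mgl2 (-1.60), genes of alternatively activated macrophages, the interleukin 33 receptor Il1rl1 (-1.72), Celf4 (-1.93) and Dync2h1 (-1.87).

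Of 13 genes of recruited and lipid-associated macrophages, Gpnmb, Spp1 and Trem2 (1.78) rose in macrophages, or 9 adjusted over the list alone, while DESeq2 called 1. The chemokine receptor Ccr2 stood at 1.35 with an adjusted p of 0.0572 (camera adjusted p = 4.64e-15, and adjusted p = 0.584 with an estimated correlation). Of 15 resident macrophage genes, Timd4 fell, or 5 adjusted over the list alone, and DESeq2 called 1, which was not Timd4, with Cd163 at -1.16 and Lyve1 at -1.15 (camera adjusted p = 0.000282, and adjusted p = 0.584 with an estimated correlation). Lists of heart muscle genes passed camera downward in macrophages too. Of 23 sarcomere genes 0 changed by edgeR, with a median of -0.51 (camera adjusted p = 0.000197, and adjusted p = 0.717 with an estimated correlation). Of 18 ion channel and calcium handling genes 0 changed, with a median of -0.48 (camera adjusted p = 0.000786, and adjusted p = 0.736 with an estimated correlation). The cause of these falls was not tested. Of 15 inflammatory genes the chemokines Ccl2 (2.20) and Ccl7 (2.06) rose by edgeR, or 3 genes adjusted over the list alone, while 4 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.0166, and adjusted p = 0.707 with an estimated correlation). The class leaves out unnamed clusters that best matched the macrophage list, among them 591 nuclei led by Gpnmb, with Spp1 and Trem2, and 181 nuclei led by Ccr2, so these genes were tested in the nuclei that remained. With those clusters joined to the class 62 genes changed, 17 of the 23 among them, the log2 fold change was 4.23 for Gpnmb in macrophage nuclei and 4.29 for Spp1 in macrophage nuclei, and the calls on Retnla and Dync2h1 were lost. Heart muscle markers in macrophages summed to 13646 and 7746 CPM in control and 7714 and 6559 CPM in cKO libraries. Between 219847 and 936248 counts were summed per library. The number of macrophage genes changed was 36 without control 1, 40 without cKO 1, 12 without control 2 and 63 without cKO 2, beside 23 in all libraries, 18 by DESeq2 and 5 with each library clustered alone. Without control 2 the calls on Spp1, Cd300lf, Nxpe5, Retnla, Celf4, Dync2h1, Il1rl1 and Mgl2 were lost. Those on Spp1 and Dync2h1 were lost without cKO 1, and those on Spp1 and Nxpe5 without cKO 2. Gpnmb measured 0 CPM in control 1, and the log2 fold change of Ctsd was 3.43 without control 2.

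**Figure D3:**
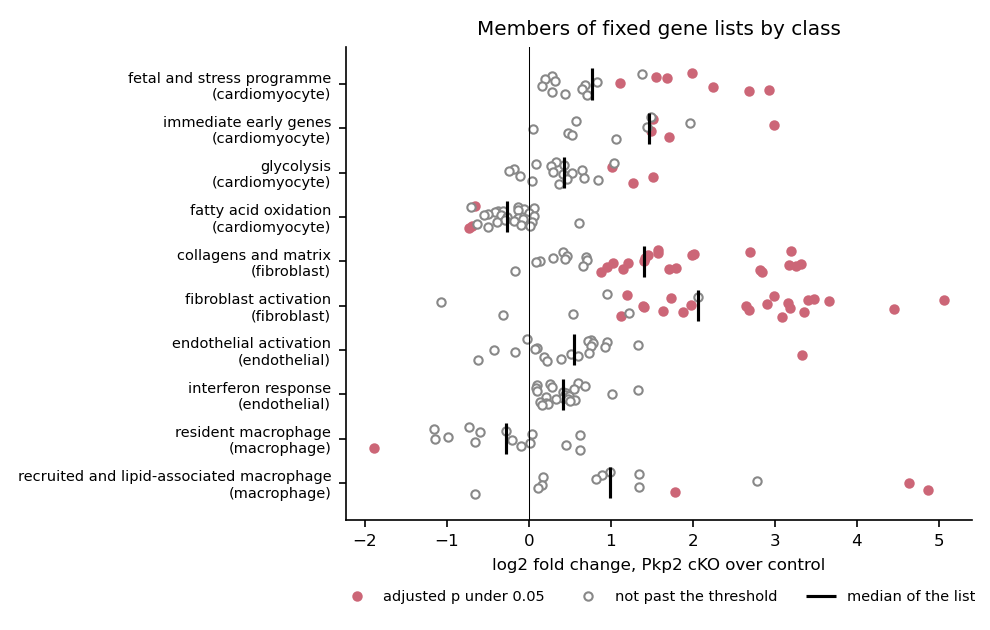
Log2 fold change (x axis, Pkp2 cKO over control) of each tested member of 10 gene lists (y axis, list and class). Red points have an adjusted p under 0.05, open points do not, and black bars are list medians, which lie at 2.07 for fibroblast activation and 1.40 for collagens and matrix in fibroblasts and at -0.26 for fatty acid oxidation in cardiomyocytes.

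The response to the cKO label was tested for differences between cardiomyocytes and each other class with an interaction term. Effects differed from those in fibroblasts for 1045 of 16309 genes, endothelial nuclei for 563 of 16320, mural nuclei for 152 of 15198 and macrophages for 199 of 15176. The rise of Nppa was larger in cardiomyocytes than in fibroblasts by 2.85 on the log2 scale (adjusted p = 5.24e-11), that of Nppb by 2.30 (1.25e-11) and that of Myh7 by 1.93 (5.24e-11). The rise of Postn was larger in fibroblasts (interaction log2 value -4.61, adjusted p = 2.74e-29). The difference for Gdf15 did not pass (2.70, adjusted p = 0.225). In this class by genotype interaction, fibroblast counts were 454 without control 2 and 618 without cKO 2. In the class by genotype interaction, endothelial counts were 359 without control 1, 280 without cKO 1, 265 without control 2 and 208 without cKO 2. In the class by genotype interaction, mural counts were 52 without control 1, 24 without control 2 and 59 without cKO 2. In the class by genotype interaction, macrophage counts were 127 without control 1, 109 without cKO 1, 95 without control 2 and 45 without cKO 2.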

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

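The tests of the sex of the nuclei and of doublets, the equal doublet share and the fits without clusters of 1 library were chosen only after the result was seen, and the interaction tests were planned.

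In the class by genotype interaction, fibroblast effects differed from those in cardiomyocytes for 1045 genes, and the other numbers were 563 for endothelial nuclei, 152 for mural nuclei and 199 for macrophages. Of the 24 cardiomyocyte genes named by the rule, 12 had an effect that differed from that in fibroblasts, 12 from that in endothelial nuclei, 7 from that in mural nuclei and 10 from that in macrophages. Leaving out control 2 gave 454, 265, 24 and 95 genes in the same order of classes, and leaving out cKO 2 gave 618, 208, 59 and 45. Leaving out control 1 gave 359, 52 and 127 genes for endothelial nuclei, mural nuclei and macrophages, and leaving out cKO 1 gave 280 for endothelial nuclei and 109 for macrophages.

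Among the nuclei outside the named classes, those that matched the macrophage list lay above the control level, while those of the other lists held 3.63% of control and 2.32% of cKO nuclei. Clusters that best matched the macrophage list but stayed unnamed held 2.41% ± 0.183 of control nuclei and 6.79% ± 3.25 of cKO nuclei (SD, n = 2). The libraries were at 2.28% and 2.54% in the control and at 9.09% and 4.50% in the cKO, and the difference was not tested. A cluster led by Gpnmb, with Spp1 and Trem2 among its leading genes, held 2.25% and 2.42% of control and 6.89% and 2.11% of cKO nuclei, so cKO 2 lay below both controls there. With an equal doublet share in every library, a cluster led by Gpnmb held 4 and 2 control and 96 and 119 cKO nuclei, and the boundaries of clusters differed from those above. A cluster led by Ccr2, a receptor of recruited monocytes, held 67 and 114 nuclei of the cKO libraries, 1.84% of each, and 0 of the control nuclei, which allows up to 0.107% and 0.0498%.

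Xist gave 5 to 12 UMIs and Y-linked genes 3299 to 8840 UMIs per library, although the design text names a mouse of each sex in each pool. If nuclei of both sexes were present and Xist were lost in counting, a large part of the cardiomyocyte nuclei with at least 3000 UMIs would lack Y-linked UMIs. The share without Y-linked UMIs was 16.7%, 15.5%, 17.2% and 11.8% in control 1, cKO 1, control 2 and cKO 2, and exceeded that of autosomal genes matched in level by 0.893 to 2.63 percentage points, which argues against that explanation. The same excess, at most 2.63 points, is what nearly all male nuclei would give, so the pools may have been male. A comparison of the sexes could not be made.

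An endothelial cluster led by Selp and a fibroblast cluster led by Cxcl1 and Il6 took 98.0% of 200 and 93.0% of 129 nuclei from cKO 2. Handling of that library that raised immediate early genes in all nuclei would put their summed CPM, not scaled with TMM factors, well above that in cKO 1 in every class, but the ratio of cKO 2 to cKO 1 ranged from 0.882 in macrophages to 1.26 in endothelial nuclei, which argues against it. Doublets would hold more UMIs than the rest of their class, but the median was 0.867 times that of the other endothelial nuclei and 0.784 times that of the other fibroblasts of the library, which argues against them. Handling that reached only part of the nuclei, and a response of the mice in that pool, were not tested and stay open. Selp in endothelial nuclei kept its call without cKO 2 (log2 fold change 2.10) and without clusters of 1 library (2.12), beside 3.33 with all nuclei, while Il6 in fibroblasts gave no value in either and Fam110d in endothelial nuclei lost its call in the latter (1.33).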

How the results depend on the processing

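The values in this part at a 20% mitochondrial limit, with an equal doublet share, without clusters mostly from 1 library and with all macrophage-like clusters come from tests chosen only after the data were seen.

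Of the 66 values of named genes, 891 alternatives kept the side of the threshold, 74 kept the direction but lost the call, and 0 reversed. Reversed means a change of sign with the main or the alternative value past the threshold. A change of sign with neither past it, as can occur for Pkp2, would count as kept. Of the 74 lost calls 24 arose with each library clustered alone, 17 without control 2, 9 with DESeq2 and 8 at the 20% mitochondrial limit. Of the counts, shares and list tests, 114 alternatives kept the side of the threshold or a count within 1.5 times, 31 gave a new call or a larger count, 41 lost the call or gave a smaller count and 3 reversed. Leaving out a library leaves 1 library in a group, whose spread is then assumed to be that of the other group.

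With no filter on low counts the genes changed numbered 792 in cardiomyocytes, 94 in endothelial nuclei, 17 in mural nuclei and 57 in macrophages, and all of the 442, 25, 2 and 23 were among them. The interaction count for mural nuclei was then 68. DESeq2 called 43 genes in endothelial nuclei, 23 of the 25 among them, and 0 in mural nuclei, where 410 had an unadjusted p under 0.05 in edgeR. With at least 1000 UMIs mural nuclei gave 4 genes. Without doublet removal the counts were 164 in endothelial nuclei, 8 in mural nuclei and 136 in macrophages, and with an equal doublet share 31 in mural nuclei and 37 in macrophages. With each library clustered alone edgeR gave 0 genes in endothelial nuclei, 0 in mural nuclei and 5 in macrophages. At the 20% mitochondrial limit the counts were 13, 1 and 89 in the same order, and doublet removal differed there too, at 10.9% in control 2 and 6.0% in cKO 2. Without the genes under 0.2 of their cardiomyocyte level, mural nuclei gave 1 gene and macrophages 39, and with all macrophage-like clusters macrophages gave 62. With an estimated correlation 0 of the 119 list tests by camera passed, and 10 had an unadjusted p under 0.05. The cause of these differences was not tested.

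With the replicate number as a block, there were 3881 cardiomyocyte genes changed, 2044 fibroblast genes changed, 833 endothelial genes changed, 126 mural genes changed and 274 macrophage genes changed, and the fibroblast share, at a log2 ratio of 0.16, passed the threshold. Of the tests of gene lists 37 passed with the block, 35 of the 40 among them. Nothing in the labels says that the numbers mark a batch. Across genes, the log2 difference between the control libraries correlated with that between the cKO libraries taken in the same order of numbers, with r of 0.468, 0.341, 0.311, 0.208 and 0.280 in the same order of classes, and genes are not independent replicates.

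The cardiomyocyte share lost its call with at least 1000 UMIs (log2 ratio -0.85) and with each library clustered alone (-0.50). The endothelial share lost it at the 1% mitochondrial limit (1.72). The mural share lost it with at least 1000 UMIs (-0.26), without doublet removal (-0.46) and with an equal doublet share (-0.39), and reversed at the 1% limit (0.35). Among nuclei other than cardiomyocytes the fibroblast (-0.26), macrophage (-0.43) and lymphocyte (-0.61) shares passed as lower, by construction with another denominator. The fibroblast and macrophage shares changed sign there and count as reversed. Among all nuclei they had not passed, with log2 ratios of 0.16 and 0.00013, so no call was overturned. With all macrophage-like clusters the macrophage share passed (0.57).

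Leaving out each library gave 304 (without control 2) to 540 fibroblast genes changed, 44 to 83 in endothelial nuclei, 0 to 68 in mural nuclei and 12 to 63 in macrophages. In the interaction test it gave 454 to 805 genes for fibroblasts, 208 to 359 for endothelial nuclei, 24 to 169 for mural nuclei and 45 to 127 for macrophages. The share log2 ratios were -0.93 to -0.54 for cardiomyocytes, 0.92 to 1.30 for endothelial nuclei and -0.71 to -0.33 for mural nuclei. The 1% mitochondrial limit left too few named nuclei for gene tests in every class. For cardiomyocytes this came from the naming rule and not from a lack of nuclei. The clusters that best matched cardiomyocytes there, the largest with 623 nuclei, stayed unnamed with under 3 markers passing. That limit therefore gave no cardiomyocyte share or gene test. The split by sex and its interaction with genotype were not run because Xist gave at most 12 UMIs in a library.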

Other observations

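The tests of pairs of genes in the same nuclei were chosen only after the gene results were seen, and that of Myh7 in nuclei without Esr1 after those of the pairs.

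In mural nuclei some lists passed camera upward and that of resident macrophages downward, although few members passed. Of 13 genes of the fetal and stress programme Acta2 rose by edgeR, or 4 genes adjusted over the list alone, while 4 had an unadjusted p under 0.05 and DESeq2 called 0, with Ccn2 at 1.69 and Fhl1 at 1.39 (camera adjusted p = 3.49e-07, and adjusted p = 0.584 with an estimated correlation). Of 24 collagens and matrix genes 0 passed by edgeR and 0 by DESeq2, 8 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone. Col4a1 stood at 1.07, Col1a1 at 1.04 and Thbs1 at 2.16 (camera adjusted p = 2.18e-07, and adjusted p = 0.707 with an estimated correlation). That call was lost without cKO 1 (0.144), and the adjusted p was 2.39e-13 to 0.144 over the left-out libraries. Of 10 resident macrophage genes in mural nuclei 0 passed by edgeR and 0 by DESeq2, 4 had an unadjusted p under 0.05 and 2 fell adjusted over the list alone, with a median of -0.74 (camera adjusted p = 0.000149, and adjusted p = 0.715 with an estimated correlation). That call was lost without control 2 (0.991) or cKO 2 (0.631), and the adjusted p was 1.10e-11 to 0.991 over the left-out libraries. Macrophage markers in mural nuclei summed to 631 and 1311 CPM in the control and 962 and 448 CPM in the cKO libraries. In macrophages, of 17 genes of autophagy and lysosome Gpnmb and Ctsd rose, or 4 adjusted over the list alone and 2 by DESeq2 (camera adjusted p = 2.25e-05, and adjusted p = 0.707 with an estimated correlation).

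Of 11179 genes tested in both cardiomyocytes and fibroblasts, 287 changed in cardiomyocytes, 379 in fibroblasts and 30 in both. The direction was the same for 28 of the 30, beside 4.96 expected for independent lists, though both classes come from the same libraries, which can add to the overlap. Heart muscle markers were also counted in fibroblasts, at 6115 to 8248 CPM per library, beside 76133 to 77113 CPM in cardiomyocytes. Whether cardiomyocyte RNA counted in fibroblast nuclei adds to the overlap was not tested. Genes that rose in both included the matricellular genes Ccn1 (log2 fold change 1.22 in cardiomyocytes and 2.67 in fibroblasts) and Ccn2 (1.69 and 2.99), the early genes Junb (1.49 and 1.68), Btg2 (1.52 and 1.76) and Nr4a1 (1.71 and 1.75), Hif1a (0.98 and 1.03) and the metallothionein Mt2 (1.66 and 2.79). Arrdc2 (-2.15 and -2.07) and the circadian output gene Hlf (-1.36 and -1.33) fell in both. Kazn (0.97 and -1.35) and Nkain2 (1.30 and -1.82) changed in opposite directions, with interaction adjusted p of 8.27e-14 and 2.18e-25. Apart from those of the rule, these genes were chosen after their values were seen.

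The rise of Esr1 and Gh in cardiomyocytes of the cKO libraries may come from reads of a transgene counted as these genes: the titles name a Cre line MCM, and if that is Mer-Cre-Mer it carries parts of the mouse estrogen receptor, often with a growth hormone end. In cKO nuclei at matched depth the odds ratio of Gh with Esr1 was 51.9 in cKO 1 and 37.2 in cKO 2, as that explanation needs. Induction with the stress genes in the same nuclei would put Gh with Nppb, but that odds ratio was 0.709 and 0.710, which argues against it for Nppb, while Gh with Myh7 gave 9.41 and 8.09 and Esr1 with Myh7 4.18 and 4.36. Whether transgene reads were counted as Myh7 as well stays open: cKO nuclei without Esr1 UMIs had 1.94 and 1.64 times the Myh7 CPM of the higher control library, between the values set for and against it. The titles put the Cre line in the controls too while their genotype tag reads wild type. Of control cardiomyocyte nuclei with at least 3000 UMIs, 86.7% and 84.3% held no Esr1 UMI, beside 30.9% and 25.4% in the cKO libraries. Over raw totals, control cardiomyocytes gave 74.4 and 62.1 CPM of Esr1, below control fibroblasts at 180 and 142 CPM. Cardiomyocytes gave 15 and 12 Gh counts in the control and 682 and 706 in the cKO libraries. If these reads are of the transgene, the values argue against its expression in control cardiomyocytes at the cKO level. The groups would then differ in transgene expression as well as in Pkp2. Whether the controls carry the transgene without such expression stays open.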
